A study of Rattus norvegicus with 84 samples.

How the data were processed

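Gene expression was measured on 84 Illumina bead arrays, 1 for each of 3 hippocampal regions of 28 male F344xBN rats aged 7 months. Per the labels' protocols, hippocampal subfields were microdissected fresh, and 0.5 µg of total RNA was amplified and biotin-labelled with the Illumina TotalPrep kit. Per the submitters' processing notes, GenomeStudio 2011.1 was used. How bead values were summarised, how background was handled and which slide held each array are not given in the sources used here. The deposited signal (intensity) table holds 22523 probes as whole numbers on a linear scale, from 36 to 41948, and no normalization or background subtraction shows in its values. Per the file headers, each array has a detection p-value for each probe. In these columns the value 0.01 stood for 0: it marked the brightest probes of every array (29.84% of entries), while the smallest other detection p-value was 0.0012, and it was read as 0. The deposited normalized table holds a score made by the authors, the log10 signal less the array's mean, divided by the array's SD (a z-score). The authors' z-score was recomputed from the deposited signal with a largest difference of 0.01302, and the series matrix held the same values (largest difference 0). A z-score sets the spread of every array to 1 value, so it removes differences of scale between arrays and has no background correction.

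Everything below was computed from the deposited signal. Background was corrected with the normexp model of limma 3.58.1 (R 4.3.3, tables read with data.table version 1.17.8), taking the mean and SD of the negative controls from the detection p-values, with an offset of 16. The log2 values were then quantile normalized over the 84 arrays. Such normalization gives every array 1 distribution, so a shift shared by most probes is removed, and the offset shrinks differences of dim probes towards 0. A probe was tested in a region if its detection p-value was under 0.01 on at least 7 of the 28 arrays, which left 9919 probes in labelled CA1, 10594 in labelled CA3, 10858 in labelled DG and 11403 over all 84 arrays. Of the 22523 probes, 13793 had 1 gene symbol and 8730 had none. The symbols named 13337 genes, of which 13297 had their Entrez number in the gene list of RefSeq. A gene with several tested probes was read from its brightest probe.

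Samples were grouped by the region, drug and behaviour of their labels, 7 arrays in each of 12 groups. Within each region, 1 limma fit (lmFit, then eBayes with a trend) of the 4 groups gave SAHA against vehicle in home cage rats and in RPC rats, RPC against home cage in vehicle rats and in SAHA rats, and the drug by behaviour interaction. Fits over all 84 arrays gave the differences between regions and F tests of whether an effect differed among the 3 regions. P-values were adjusted by Benjamini-Hochberg within a contrast, and a probe was called at an adjusted p under 0.05. The 28 arrays of a region came from different rats, so these p-values measure the spread between rats. The number of rats, 7 per group, limits the precision. Gene lists were tested with camera of limma at a preset correlation of 0.01 and again with a correlation estimated from the data, over 36 lists (23 pathways or complexes and 13 sets of cell type markers). A list's members were counted as called over all probes and again when adjusted over the list alone.

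The groups, contrasts, tests, thresholds, gene lists and most alternatives were fixed before the data were examined. So was the rule for naming genes: the 5 largest rises and 5 largest falls among called genes of a contrast, the 3 smallest p-values where none passed, up to 4 members of each list, 12 fixed genes, and the genes called in all 3 regions. Of the fixed genes, Homer1 and H1f0 had no named probe, Nr4a1 and Cdkn1a were too dim to be tested, and Npas4 was not tested in labelled CA1. The alternatives fixed in advance were the authors' z-scores, no background correction, median scaling, no filter, a strict filter (detected on every array), array weights, the replicate number as a block, and all 84 arrays in 1 fit with the rat as a random block. For that block, here and below, arrays of the same drug, behaviour and replicate number were taken as 1 rat. The labels do not say that a number marks 1 rat in the 3 regions. A block for the slide was not run. After the data had been seen, 3 alternatives were added: a fit without 8 arrays whose correlation with the rest of their region lay over 5 median absolute deviations under the median, a contrast of SAHA and vehicle averaged over regions and behaviours, and fits that left out each of the 84 arrays in turn. Before every array was left out in turn, the 3 arrays of SAHA RPC replicate 1 had been left out together after their Tmem252 values were seen. That fit chose arrays by an outcome, and its values are not used. Replicate numbers did not pair arrays across compared groups: the mean correlation of same-numbered arrays between groups ran from -0.210 to 0.171 over 12 comparisons.

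The fit was tested on simulated data drawn from each probe's mean and residual spread on the real arrays, with 100 probes changed by each of 2 sizes. For RPC against home cage in vehicle rats, a change of 0.5 on the log2 scale was recovered for 76% of changed probes in labelled CA1, 52% in labelled CA3 and 88% in labelled DG, and a change of 1 for 96%, 87% and 100%. There were 4, 6 and 7 false calls. The F test recovered 88.5% of 200 probes changed by 1 in labelled DG alone, with 18 false calls over 11403 probes. Each simulated probe was drawn independently of the others, with 1 spread for all arrays. Probes that move together and arrays of poor quality were not simulated, so these shares and false calls do not cover them. Of every fit, 100 splits of the arrays (the real one included) were drawn to see how often another grouping gave as many calls.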

Results

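Gene expression in the rat hippocampus was measured on 84 arrays, 1 for each of 3 regions of 28 rats. The regions were labelled CA1, CA3 and DG (dentate gyrus). The rats formed 4 groups of 7: they were injected with SAHA, which inhibits histone deacetylases, at 50 mg/kg or with its solvent DMSO (vehicle). They stayed in the home cage or swam in a water maze. The maze session, called RPC for redundant place and cue information, took 17 trials from 10 min after the injection, with a probe trial of 60 s, and all rats were killed 90 min after the injection. RPC rats had learned the maze over 8 days of training a week before and home cage rats had not, so each comparison of RPC with home cage includes that training. Every rat was injected, so no value shows the level without an injection. The share of probes detected averaged 41.96 ± 1.26% (SD, n = 28) in labelled CA1, 44.01 ± 2.27% in labelled CA3 and 46.41 ± 1.06% in labelled DG. The array's mean signal ran from 428.2 to 904.8. Array Veh RPC replicate 6 of labelled CA3 had the lowest share detected (35.35%) and a median correlation of 0.814 with the other arrays of its region.

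Known markers of the 3 regions were read first, as a check of the labels. Wfs1, a marker of CA1 pyramidal neurons, had a mean log2 level of 6.86 ± 0.77 (SD, n = 28) on arrays labelled CA1 and 10.65 ± 0.29 on arrays labelled DG, a difference of -3.79 ± 0.19 (SE, limma adjusted p = 8.09e-30). Ccn3 was lower by as much (-3.79), and Mpped1, also known from CA1 neurons, was detected on 0 of 28 arrays labelled CA1 and on 28 of 28 labelled DG, at least 3.79-fold lower. The reverse held for dentate granule cells: Prox1, their transcription factor, was higher in labelled CA1 than in labelled DG by 1.08, C1ql2 by 2.50 and Sema5a by 1.77. Prox1 was detected on 28 of 28 arrays labelled CA1 and on 4 of 28 labelled DG, so the size of its difference rested on values near background. Of 8 measured CA1 neuron markers, 7 were lower and 1 was higher in labelled CA1 than in labelled DG (adjusted p = 1.9e-05, and adjusted p = 0.0234 with an estimated correlation). Of 6 granule cell markers, 5 were higher and 1 was lower (adjusted p = 0.0103, but adjusted p = 0.159 with an estimated correlation). The exceptions were Htr1a, higher in labelled CA1 by 1.57, and Pkp2, lower by 1.31 (a difference of -1.31). CA3 neuron markers were highest in labelled CA3: Nectin3 was at 8.58 in labelled CA3 against 6.87 in labelled CA1 and 5.88 in labelled DG, and 5 of 6 measured markers were higher in labelled CA3 than in labelled DG (adjusted p = 0.00709 with an estimated correlation). Against labelled CA1 it was again 5 of 6, but the list was lost (adjusted p = 0.149 with an estimated correlation). All 28 arrays labelled CA1 had a lower score of CA1 markers less granule cell markers than all 28 labelled DG (-1.54 ± 0.30 against 1.44 ± 0.30, mean and SD). The deposited labels are kept throughout, written as labelled CA1 and labelled DG, and no statement on either assumes which tissue it held.

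**Figure D1:**
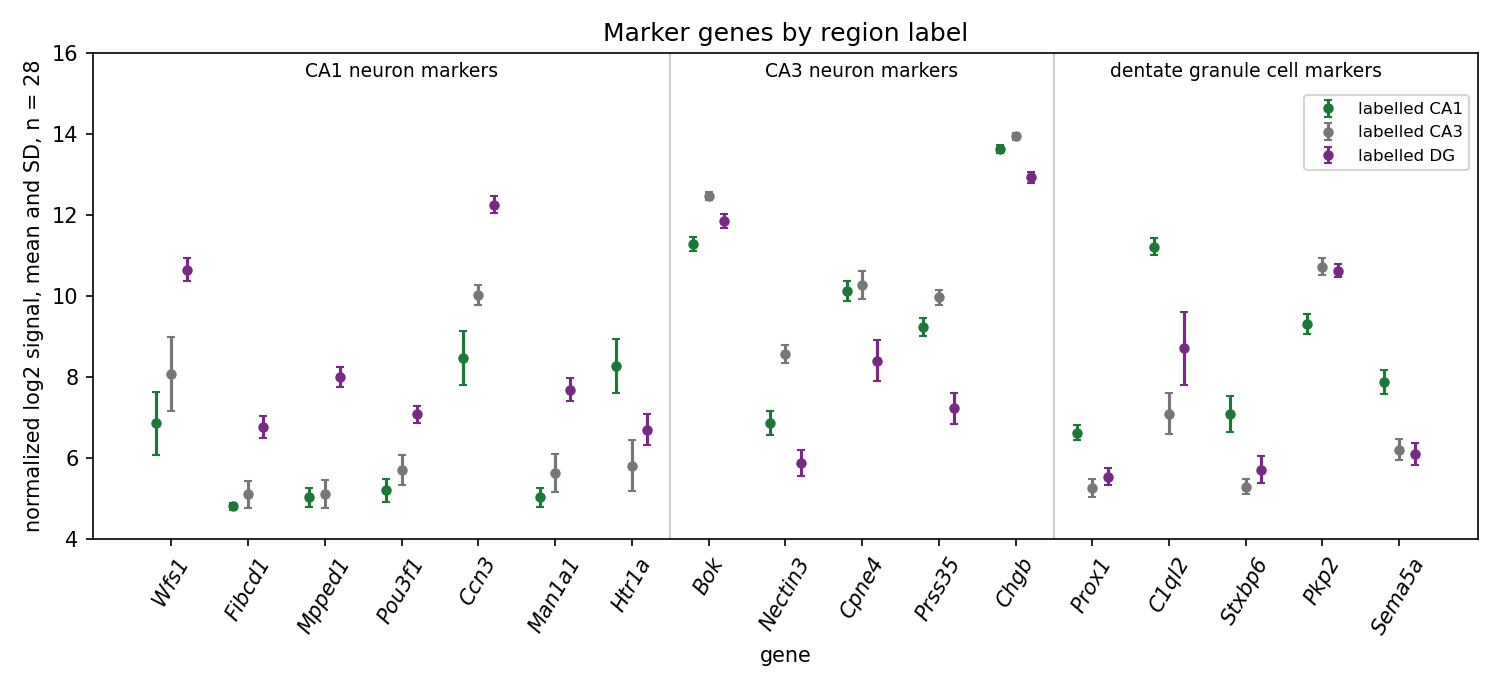
Each gene's normalized log2 signal (vertical axis) by region label (colour), as the mean and SD of 28 arrays, for markers of CA1 neurons, CA3 neurons and dentate granule cells. Wfs1 averaged 6.86 on arrays labelled CA1 and 10.65 on arrays labelled DG, and C1ql2 averaged 11.22 and 8.72.

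Over all probes the regions differed widely. Of 11403 probes, 9197 differed between labelled CA1 and labelled CA3 (4546 higher, 4651 lower), 8254 between labelled CA1 and labelled DG (4140 higher, 4114 lower) and 8595 between labelled CA3 and labelled DG (4483 higher, 4112 lower). Differences over 2-fold numbered 1087, 524 and 698. C1ql2 was among the largest, 4.13 higher on the log2 scale in labelled CA1 than in labelled CA3. Oligodendrocyte markers were lower in labelled CA1 than in labelled DG for 12 of 13 genes, which was not past the threshold as a list with an estimated correlation (adjusted p = 0.092 with an estimated correlation). These fits treat the 3 arrays of a rat as independent.

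The comparison of SAHA with vehicle in home cage rats asked what the drug did without a maze session. Tmem252, which codes for a transmembrane protein, was lower in SAHA rats in all 3 regions, with 7 of 7 SAHA arrays under every vehicle array in each region. In labelled CA1 its mean log2 level was 6.84 ± 0.34 (SD, n = 7) with vehicle and 5.10 ± 0.20 with SAHA, a fitted change of -1.74 ± 0.19 (SE, limma adjusted p = 4.89e-06). In labelled CA3 it changed by -1.59 ± 0.22 (adjusted p = 0.00129) and in labelled DG by -1.70 ± 0.21 (adjusted p = 3.99e-05). SAHA arrays detected it 0 of 7 times in labelled CA1 and in labelled CA3, so it was at least 1.63-fold and at least 2.0-fold lower there. In labelled DG they detected it 2 of 7 times. In labelled DG, Slc19a3, a thiamine transporter, fell by 0.55 ± 0.10, and Nfkbia, the inhibitor that holds NF-kappa-B in the cytoplasm, fell by 0.47 ± 0.08 (adjusted p = 0.0171 for both). Slc19a3, detected on 3 of 7 SAHA arrays, was lower on 7 of 7 SAHA arrays than on every vehicle array, and Nfkbia on 6 of 7. These were all the calls: 1 of 9919 probes in labelled CA1, 1 of 10594 in labelled CA3 and 3 of 10858 in labelled DG, while 710, 52 and 702 had an unadjusted p under 0.05 and chance alone gives 496, 529.7 and 542.9. In labelled CA3 the 52 lay far under chance. The fit gave all groups of a region 1 spread, and in labelled CA3 all arrays of low correlation were RPC arrays. The single call there therefore does not show that the drug's effect was weak. Without SAHA HC replicate 3 or 4 the count in labelled CA1 was 4, and without SAHA HC replicate 6 or vehicle HC replicate 1 it was 2. In labelled DG it was 1 without SAHA HC replicate 5 or vehicle HC replicate 3, 6 without SAHA HC replicate 7 or vehicle HC replicate 6, 13 without SAHA HC replicate 3 and 16 without vehicle HC replicate 7, and Slc19a3 lost its call in 3 and Nfkbia in 4 of the 14 such fits. The call of Nfkbia also ended with median scaling (adjusted p = 0.0998, range over settings 0.00553 to 0.0998).

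Gene groups moved little in home cage rats. Glucocorticoid-responsive genes were tested after SAHA in labelled DG, where 1 of 17 measured genes fell, Nfkbia (1 adjusted over the list alone), and 0 rose, with a median change of -0.10 (adjusted p = 0.000106, but adjusted p = 0.341 with an estimated correlation). In labelled CA3 their median was -0.08 with 0 of 18 called (adjusted p = 0.000242, but adjusted p = 0.167 with an estimated correlation), and in labelled CA1 it was -0.04 with 0 of 15 called (adjusted p = 0.868 with an estimated correlation). Immediate early genes, which neurons switch on within minutes of activity, had a median of -0.08 in labelled CA1 with 0 of 22 called, and 2 lower when adjusted over the list alone (adjusted p = 0.0422, but adjusted p = 0.868 with an estimated correlation). Gadd45g, a stress-induced gene, had the smallest p of that list, with -0.59 ± 0.12 (adjusted p = 0.085 over all probes). Endothelial markers in labelled CA1 had a median of -0.15 with 0 of 5 called (adjusted p = 0.868 with an estimated correlation). In labelled CA3, interneuron markers were at 0.13, oligodendrocyte markers at -0.09 and choroid plexus markers at 0.30 in the median, with no member called (adjusted p = 0.167, 0.508 and 0.299 with an estimated correlation). A list of 14 genes known to respond to histone deacetylase inhibitors was not past the threshold with SAHA. Its adjusted p was 0.495, 0.909 and 0.793 in labelled CA1, CA3 and DG of home cage rats, and 0.411, 0.997 and 0.421 in RPC rats. These p-values do not show that the drug left such genes unchanged. Of the fixed genes, H1f0 had no named probe and Cdkn1a was too dim to be tested, so neither could be read. Hdac2, a target of SAHA, was not called with the drug in any region.

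The comparison of SAHA with vehicle in RPC rats asked for the drug's effect when it was followed by a maze session. Tmem252 was lower again, by -1.28 ± 0.19 in labelled CA1 (SE, n = 7, adjusted p = 0.00239, 7 of 7 arrays under the vehicle mean) and by -1.21 ± 0.21 in labelled DG (adjusted p = 0.00812, 6 of 7 arrays). SAHA arrays detected it 1 of 7 times in labelled CA1 and 5 of 7 times in labelled CA3 and in labelled DG, so the sizes of these falls rested on values near background. In labelled DG, Apold1, an early response gene of blood vessel endothelium, rose by 0.70 ± 0.11 (adjusted p = 0.00221, 7 of 7 SAHA arrays over every vehicle array). Also in labelled DG, the iron exporter Slc40a1 rose by 0.47 ± 0.09, the endothelial receptor Tie1 by 0.40 ± 0.08 and Csrp2 by 0.48 ± 0.10, while Slc19a3 fell by 0.59 ± 0.10, Kank3 by 0.52 ± 0.09 and the cAMP-responsive transcription factor Crem by 0.33 ± 0.06. Slc19a3 was detected on 1 of 7 SAHA arrays. In labelled CA1, Phf13, a reader of histone marks, rose by 0.47 ± 0.09, and Cldn5, a tight junction protein of brain endothelium, fell by 0.36 ± 0.07, the RNA exosome gene Exosc3 by 0.35 ± 0.07 and Yeats4 by 0.31 ± 0.06. Counts were 6 of 9919 (1 higher, 5 lower) in labelled CA1, 0 of 10594 in labelled CA3 and 9 of 10858 (4 higher, 5 lower) in labelled DG, and 1049, 538 and 689 probes had an unadjusted p under 0.05. In labelled CA3 limma called no gene, the array-weighted fit called 1 and the fit of all 84 arrays 11: the smallest p-values were those of Tmem252 (-1.16 ± 0.22), Ctsk (-0.52) and Itpka (-0.35), each with an adjusted p of 0.192.

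Tmem252 in labelled CA1 and in labelled DG, and Apold1, Slc19a3 and Kank3 in labelled DG, stayed called whichever of the 14 arrays was left out. Other calls of this comparison depended on single arrays or on the fit. In labelled CA3 Tmem252 was called in 1 of the 14 fits without an array, that without SAHA RPC replicate 1 (-1.36, adjusted p = 0.00115, range over the 14 fits up to 0.556), where 4 probes passed. It was also called there with all 84 arrays in 1 fit (adjusted p = 0.0128) and with array weights (-1.38, adjusted p = 0.0175), in a range over settings up to 0.844. In labelled CA1 the count was 65 without vehicle RPC replicate 3 and 16 without SAHA RPC replicate 1. It was 3 without vehicle RPC replicate 2 or 4, 2 without vehicle RPC replicate 5 or SAHA RPC replicate 3, and 1 without SAHA RPC replicate 4, 5, 6 or 7 or vehicle RPC replicate 1, 6 or 7. In labelled DG it was 22 without SAHA RPC replicate 1, 4 without SAHA RPC replicate 3, 4 or 7, and 5 without SAHA RPC replicate 6 or vehicle RPC replicate 3. Phf13 lost its call in 10 of 14 such fits, Cldn5 in 9, Exosc3 in 10, Yeats4 in 12, Csrp2, Slc40a1 and Tie1 in 11 each and Crem in 6. With all 84 arrays in 1 fit, the calls in labelled DG of Kank3 and Tie1 (adjusted p = 0.9997 each), Csrp2 (0.62), Crem (0.519) and Slc40a1 (0.327) ended, where the range over settings began at 0.00414. With median scaling those in labelled CA1 of Phf13, Cldn5, Exosc3 and Yeats4 ended (adjusted p = 0.237, 0.21, 0.369 and 0.376, range over settings from 0.0079), and with the replicate number as a block those of Phf13, Exosc3 and Yeats4 did (0.0711 each).

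Cell type markers and lists moved little with SAHA in RPC rats: astrocyte markers in labelled CA1 had a median of -0.12 with 0 of 9 called and 1 lower when adjusted over the list alone (adjusted p = 0.00573, but adjusted p = 0.0783 with an estimated correlation), and microglia markers in labelled DG a median of 0.13 with 0 of 13 called (adjusted p = 0.639 with an estimated correlation). In labelled CA3 oligodendrocyte markers were at 0.28 and interneuron markers at -0.15 (adjusted p = 0.474 and 0.623 with an estimated correlation), and glucocorticoid-responsive genes in labelled CA1 were at -0.07 (adjusted p = 0.555 with an estimated correlation).

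**Figure D2:**
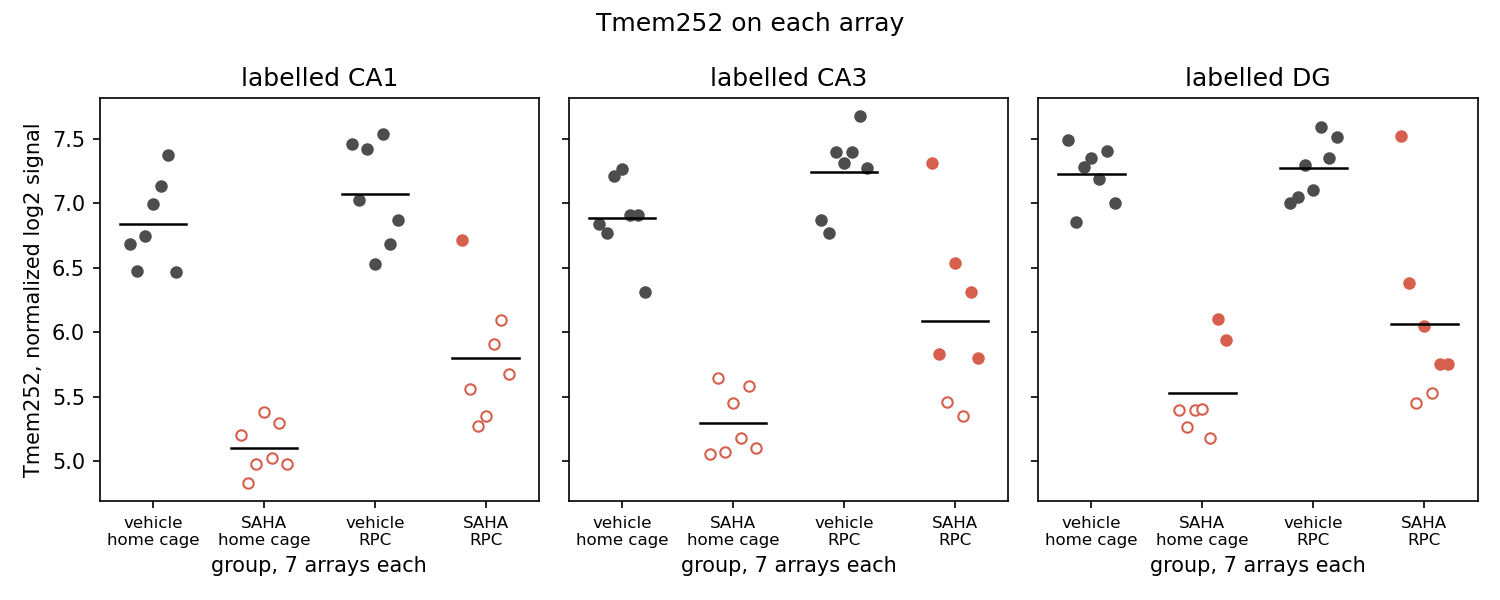
Normalized log2 signal of Tmem252 (vertical axis) on each of the 84 arrays by group, 7 arrays per group and region, with the group mean as a line. Filled points were detected and open points were not; in home cage rats all 7 SAHA arrays of each region lay under all 7 vehicle arrays.

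RPC against home cage in vehicle rats asked which genes a maze session changed without the drug. Immediate early genes rose in all 3 regions. In labelled DG, Fos rose by 1.35 ± 0.17 (SE, n = 7, adjusted p = 7.3e-06), the neuronal activity factor Npas4 by 1.31 ± 0.15 (adjusted p = 2.64e-06), Egr4 by 1.05 ± 0.11 and the histone demethylase Kdm6b by 0.89 ± 0.10, each higher on 7 of 7 RPC arrays than on every home cage array. Npas4 was detected on 1 of 7 home cage and 7 of 7 RPC arrays. Junb and Arc, a regulator of synaptic strength, were called in all 3 regions. Junb rose by 0.60 ± 0.09 in labelled CA1, 1.16 ± 0.17 in labelled CA3 and 0.91 ± 0.07 in labelled DG, and Arc by 0.98 ± 0.16, 0.95 ± 0.16 and 0.86 ± 0.13. In labelled CA1, Fos rose by 1.11 ± 0.16 (adjusted p = 0.000372, detected on 4 of 7 home cage arrays), the orphan nuclear receptor Nr4a2 by 0.91 ± 0.13, Pik3c2a by 0.89 ± 0.19 and Sgk1, a stress-hormone-induced kinase, by 0.26 ± 0.08. Ints2 rose there by at least 1.24-fold (0 of 7 home cage arrays detected it). Jun, in contrast, fell there by 0.42 ± 0.06. Of the immediate early genes, 10 of 22 measured rose and 1 fell in labelled CA1 (14 and 1 adjusted over the list alone; median 0.38, adjusted p = 0.0126 with an estimated correlation). In labelled CA3 2 of 25 rose (11 adjusted over the list alone; median 0.36, adjusted p = 0.00277 with an estimated correlation), and in labelled DG 12 of 25 (19 adjusted over the list alone; median 0.47, adjusted p = 1.01e-05 with an estimated correlation).

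Labelled CA1 of vehicle rats had the most calls, 639 of 9919 probes (244 higher, 395 lower), against 2 of 10594 in labelled CA3 (both higher) and 35 of 10858 in labelled DG (32 higher, 3 lower). At an unadjusted p under 0.05 there were 2362, 2100 and 917. This order changed with all 84 arrays in 1 fit and the rat as block, where labelled CA3 had 2299 calls (1015 higher, 1284 lower) and labelled CA1 469. That fit takes 1 spread per probe over the 3 regions. In labelled CA3, 3 of 7 vehicle RPC arrays had a low correlation, so the p-values of that fit may be too small there. With array weights labelled CA3 had 429 and labelled CA1 still had more, 1373. The largest falls in labelled CA1 were those of Tmem109 (-0.63 ± 0.15, SE, n = 7), the nuclear receptor coactivator Ncoa6 (-0.58 ± 0.13), Phf23 (-0.57), Spag7 (-0.56) and Lgals3bp (-0.56), each lower on 7 of 7 RPC arrays than the home cage mean. In labelled DG the splicing factor gene Snw1 fell by 0.31 ± 0.06 and Tm4sf1 by 0.41 ± 0.09. Of genes of the proteasome and of oxidative phosphorylation in labelled CA1, 4 of 21 and 4 of 25 fell and 0 rose (6 each adjusted over the list alone), among them Psma5 (-0.23) and Psmd1 (-0.25), Atp5pd (-0.26) and Sdhc (-0.17). Their medians were -0.09 and -0.07, and both lists were lost with an estimated correlation (adjusted p = 0.425 and 0.473 with an estimated correlation). Astrocyte markers rose there, 2 of 9 (3 adjusted over the list alone), Slc4a4 by 0.64 and Gja1 by 0.20, with a median of 0.13 (adjusted p = 0.0266 with an estimated correlation), and members of the synapse lists rose as well, Syn2 by 0.59, Rims2 by 0.56 and Camk2b by 0.29, without a shift of those lists.

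The falls in labelled CA1 depended on the scaling. With median scaling 124 probes were called there, 1 of them lower and the others higher. The calls of Tmem109 (adjusted p = 0.0949, range over settings 0.00639 to 0.0949), Ncoa6, Phf23, Spag7 and Lgals3bp ended, with each still lower (-0.53 to -0.45). The count was 328 without vehicle RPC replicate 6, 415 without vehicle HC replicate 6 and 425 without vehicle RPC replicate 2. In labelled CA3, 5 of 28 arrays had a low correlation and bore on the calls: without them Fos was called (1.00, adjusted p = 0.0442, range over settings from 0.00349), Arc was not (0.81, adjusted p = 0.183, range 0.000168 to 0.195) and Junb was not (0.88, adjusted p = 0.0593, range 4.79e-11 to 0.0593). With all arrays Fos changed there by 0.64 ± 0.33 and did not pass (adjusted p = 0.26), and without vehicle RPC replicate 6 of labelled CA3 it did (adjusted p = 0.000545), with 4 probes called. In labelled DG the count was 23 without vehicle HC replicate 7. Sgk1 in labelled CA1 lost its call in 9 of 14 fits without 1 array, and Tm4sf1 in labelled DG in 8. The call of Snw1 in labelled DG ended with median scaling (adjusted p = 0.101, range over settings 0.00394 to 0.9999) and in the fit of all 84 arrays, that of Tm4sf1 in the fit of all 84 arrays (adjusted p = 0.191, range from 0.0253) and that of Sgk1 in 5 of 9 settings (range 0.0131 to 0.225). The median change of all probes in labelled CA3 was 0.0417 in vehicle rats and 0.00683 in SAHA rats, and with median scaling it was 0.106 and 0.136.

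Of the other lists in vehicle rats, 1 passed both tests with RPC. Genes known to respond to histone deacetylase inhibitors rose in labelled DG, 2 of 14 (4 adjusted over the list alone): Klf2, a shear-stress factor, by 0.51 and Gadd45b by 0.38, with a median of 0.15 (adjusted p = 0.000714 with an estimated correlation). In labelled CA3 0 of 14 rose (3 adjusted over the list alone; median 0.19, adjusted p = 0.787 with an estimated correlation), as did 0 of 11 inflammation genes (3 adjusted over the list alone; median 0.25, adjusted p = 0.787 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.14 in labelled DG, where 1 of 17 rose (2 adjusted over the list alone), the clock gene Per1 by 0.38 (adjusted p = 0.0966 with an estimated correlation), and of 0.10 in labelled CA1, where 1 of 15 rose, Sgk1 (4 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation).

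RPC against home cage in SAHA rats asked the same of rats that had the drug. Dusp1, a phosphatase that switches off MAP kinases, and Ier2 rose in all 3 regions. Dusp1 rose by 1.23 ± 0.15 (SE, n = 7, adjusted p = 4.12e-05) in labelled CA1, 0.88 ± 0.15 (adjusted p = 0.0193) in labelled CA3 and 1.10 ± 0.12 (adjusted p = 2.1e-06) in labelled DG, and was higher on 7 of 7 RPC arrays than on every home cage array in each. Ier2 rose by 0.73 ± 0.15, 0.71 ± 0.12 and 0.69 ± 0.13. Apold1 rose by 0.83 ± 0.14 in labelled CA1 (adjusted p = 0.00212) and by 0.93 ± 0.11 in labelled DG (adjusted p = 2.1e-06), and Plat, the tissue plasminogen activator, by 0.52 ± 0.10 in labelled CA3. Fos rose by 0.80 ± 0.16 in labelled CA1 and 1.14 ± 0.17 in labelled DG, where Npas4 rose by 0.90 ± 0.15 (detected on 1 of 7 home cage arrays) and Gadd45g by 0.91 ± 0.14. Egr1 rose by 0.47 in labelled CA1, Arc by 0.60 and Hdac2 by 0.29.

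**Figure D3:**
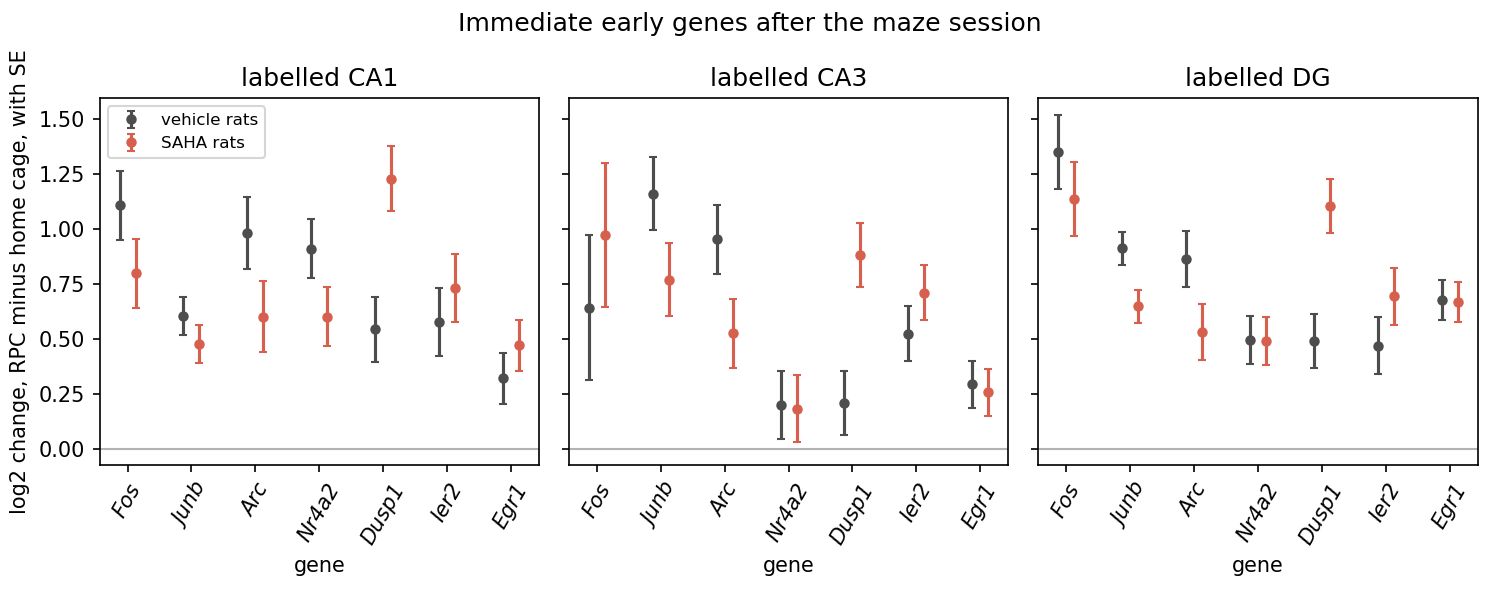
Change of 7 immediate early genes with RPC, as the log2 difference from home cage and its SE (vertical axis, 7 against 7 arrays), in vehicle rats and SAHA rats by region label. Dusp1 stood at 1.23, 0.88 and 1.10 in SAHA rats of labelled CA1, CA3 and DG and at 0.54, 0.21 and 0.49 in vehicle rats.

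In SAHA rats 249 of 9919 probes were called in labelled CA1 (175 higher, 74 lower) and 3 of 10594 in labelled CA3 (all higher). In labelled DG 1.446% of 10858 were called, 26 of them lower and the others higher, and 1535, 418 and 1510 had an unadjusted p under 0.05. The other large rises in labelled CA1 were those of the ATP synthase subunit Atp5mk (1.05 ± 0.23), the growth factor Ptn (0.90 ± 0.21) and Fam110d (at least 1.06-fold). The largest falls there were the synaptic vesicle gene Syngr1 (-0.59 ± 0.15), Clec1a (-0.54), Fgf12 (-0.52), the histone demethylase Kdm5b (-0.48) and Mss51 (-0.47). Syngr1 was detected on 6 of 7 home cage and 3 of 7 RPC arrays, and Clec1a on 4 and 1 of 7. In labelled DG they were Tsn (-0.74 ± 0.19), Nrep (-0.65 ± 0.13), Enc1 (-0.60), Phyhip (-0.51) and Cdh13 (-0.48). Each of these was beyond the home cage mean on 7 of 7 RPC arrays. Fewer arrays lay beyond every home cage array for most of them. That count was 2 of 7 for Tsn, Enc1 and Kdm5b and 3 for Syngr1, Phyhip and Mss51. It was 5 for Ptn and Fgf12, 6 for Fam110d, Clec1a and Cdh13 and 7 for Atp5mk and Nrep. Leaving out 1 array at a time, the count in labelled CA1 was 102 without SAHA RPC replicate 5 and 122 without SAHA HC replicate 7. It was 0.622 of itself without SAHA RPC replicate 7, 0.631 without SAHA HC replicate 1 and 0.647 without SAHA RPC replicate 3, and 552 without the arrays of low correlation. In labelled DG it was 98 without SAHA HC replicate 2, 100 without SAHA HC replicate 5 or SAHA RPC replicate 7, and 254 without SAHA HC replicate 7. In labelled CA3 it was 0 without SAHA RPC replicate 1, 2 or 6 and 1 without SAHA HC replicate 2, 4 or 5. Dusp1 lost its call there in 3 of 14 such fits, Ier2 in 7 and Plat in 11. In labelled CA1 Arc lost its call in 10, Mss51 in 9, Hdac2 in 7, Fgf12 in 6 and Syngr1, Kdm5b and Egr1 in 5, and in labelled DG Phyhip lost it in 10 and Tsn and Enc1 in 9. With the replicate number as a block the calls in labelled CA3 ended for Dusp1 (adjusted p = 0.0636, range over settings from 0.000422), Ier2 and Plat (0.111 each, range from 0.000837), and that of Dusp1 also with the authors' values. The same block ended those of Enc1 (0.0676, range over settings 0.0147 to 0.9756) and Phyhip (0.0529, range 0.0072 to 0.891) in labelled DG. In the fit of all 84 arrays those of Fos (0.0727), Atp5mk, Ptn, Fgf12 and Mss51 in labelled CA1 and of Arc, Tsn, Nrep, Enc1 and Phyhip in labelled DG ended (0.0583 to 0.9756, range over settings from 0.000196). With median scaling those of Arc in labelled CA1 and DG, Hdac2, Syngr1, Fgf12 and Mss51 in labelled CA1 and Cdh13 in labelled DG ended (0.0577 to 0.202, range over settings from 0.00132).

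Immediate early genes rose as a group in SAHA rats too. In labelled CA1 10 of 22 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.41, adjusted p = 0.00214 with an estimated correlation). In labelled CA3 2 of 25 rose, Dusp1 and Ier2 (10 adjusted over the list alone; median 0.27, adjusted p = 1.44e-05 with an estimated correlation), and in labelled DG 17 of 25 (20 adjusted over the list alone; median 0.50, adjusted p = 5.36e-05 with an estimated correlation). Glucocorticoid-responsive genes rose in labelled DG, 4 of 17 (8 adjusted over the list alone): Per1 by 0.48, the metal-binding protein Mt1 by 0.46, Nfkbia by 0.39 and Mfsd2a by 0.29, with a median of 0.29 (adjusted p = 0.012 with an estimated correlation). In labelled CA3 0 of 18 were called over all probes and 4 rose when adjusted over the list alone (median 0.17, adjusted p = 0.0279 with an estimated correlation), and in labelled CA1 1 of 15 rose (median 0.18, adjusted p = 0.51 with an estimated correlation). These rises were measured from SAHA home cage arrays. In labelled DG, Nfkbia was lower there than with vehicle (-0.47, against -0.24 in RPC rats), so its rise began from a lower level. How much of the list's rise came from such a level was not tested. Genes known to respond to histone deacetylase inhibitors rose in labelled DG, 3 of 14 (5 adjusted over the list alone), Klf2 by 0.88, Klf4 by 0.82 and Mt1 by 0.46 (adjusted p = 0.00366 with an estimated correlation), and in labelled CA3 0 of 14 were called (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.146 with an estimated correlation). Mt1 counted in this list and in the glucocorticoid-responsive list, so the calls of these lists in labelled DG are not separate results. Of presynaptic genes in labelled CA1, 1 of 16 fell, Syt1 by 0.17 (1 adjusted over the list alone; median -0.19, adjusted p = 0.0942 with an estimated correlation).

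No list of cell type markers passed with an estimated correlation for RPC in SAHA rats. Microglia markers were at 0.10 in the median in labelled DG, where 2 of 13 rose, the complement genes C1qc by 0.27 and C1qb by 0.21 (4 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). Oligodendrocyte markers were at 0.12 in labelled DG (0 of 12 called, 2 higher adjusted over the list alone; adjusted p = 0.628 with an estimated correlation) and at 0.36 in labelled CA3 (0 of 13 called, 4 higher adjusted over the list alone; adjusted p = 0.0812 with an estimated correlation). Interneuron markers were at -0.14 in labelled CA3 (0 of 12 called; adjusted p = 0.206 with an estimated correlation). The inflammation list in labelled CA3 was at 0.19 (adjusted p = 0.255 with an estimated correlation), and in labelled DG the glycolysis and hypoxia list was at -0.05 and the oligodendrocyte precursor list at 0.12 (adjusted p = 0.359 and 0.443 with an estimated correlation). With an estimated correlation the list calls that held within regions were those of immediate early genes with RPC in all 3 regions and both drug groups, astrocyte markers with RPC in labelled CA1 of vehicle rats, glucocorticoid-responsive genes with RPC in labelled CA3 and DG of SAHA rats, and genes that respond to histone deacetylase inhibitors with RPC in labelled DG of both drug groups. The call of glucocorticoid-responsive genes may hold in part a lower level in SAHA home cage rats.

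Whether the drug changed the response to RPC was tested by the interaction. Apold1 was called in labelled DG: RPC raised it by 0.93 ± 0.11 in SAHA rats, its change in vehicle rats was 0.04, and the interaction was 0.89 ± 0.15 (SE, limma adjusted p = 0.0141). In labelled CA1 its interaction was 0.75 ± 0.20 (adjusted p = 0.575) and in labelled CA3 0.44 ± 0.24 (adjusted p = 0.884). Dusp1 had interactions of 0.69 ± 0.21, 0.67 ± 0.21 and 0.61 ± 0.17 in labelled CA1, CA3 and DG and did not pass (adjusted p = 0.575, 0.884 and 0.999). Its level in home cage rats was lower with SAHA, -0.63 ± 0.15, -0.53 ± 0.15 and -0.51 ± 0.12, and did not pass either (adjusted p = 0.247, 1 and 0.111). In labelled CA1 the 1 called probe, ILMN_1350899, has no gene symbol. It stood at 5.79 in vehicle and 6.36 in SAHA home cage rats, and at 6.27 and 5.80 after RPC (adjusted p = 0.0442). It was detected on 0, 5, 7 and 1 of 7 arrays of these groups in that order, so the size of its interaction was not read. In labelled CA3 limma called 0 of 10594 probes (232 with an unadjusted p under 0.05), and no setting called any. Ccn2 (-0.75), Ctsk (-0.53) and Itpka (-0.39) had the smallest p-values there, and Apoo (0.31), Polg2 (0.42) and Wdr33 (0.44) were next in labelled CA1. The call of Apold1 ended with the replicate number as a block (adjusted p = 0.11, range over settings 0.00557 to 0.423), and that of ILMN_1350899 without any 1 of 23 of the 28 arrays. Without SAHA HC replicate 3 the count in labelled DG was 2. Microglia markers in labelled DG had an interaction median of 0.15, and oligodendrocyte and interneuron markers in labelled CA3 of 0.43 and -0.30 (adjusted p = 0.418, 0.194 and 0.194 with an estimated correlation).

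The RPC responses of vehicle and SAHA rats, which share no arrays, were compared gene by gene. In labelled DG 22 of the 32 probes that rose in vehicle rats also rose in SAHA rats, where independence gives 0.386, and in labelled CA1 39 rose in both (4.305 by independence) and 28 fell in both (2.947). Of the labelled CA1 probes called in vehicle rats, 220 of 244 that rose and 365 of 395 that fell lay on the same side in SAHA rats. Across these genes, which were chosen as called in vehicle rats and are not independent replicates, the changes correlated with r = 0.745 in labelled CA1 and 0.943 in labelled DG. Over all probes r was 0.306 in labelled CA1, 0.713 in labelled CA3 and 0.6 in labelled DG. In labelled CA3 the arrays of low correlation were 3 of vehicle RPC and 2 of SAHA RPC, and 0 of home cage rats. Array quality thus ran with RPC in both drug groups there, and r = 0.713 cannot tell it apart from a shared response. Labelled CA1 and labelled DG of vehicle rats shared 16 risen probes (0.746 by independence). Both regions came from the same vehicle rats, so a difference between those rats could show in both. The number by independence is therefore no fair measure for this pair.

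Whether an effect differed among regions was tested by F tests over all 84 arrays. The response to RPC in vehicle rats differed for 629 of 11403 probes, led by Arsl (0.64 in labelled CA1, -0.65 in labelled CA3, 0.49 in labelled DG), Tmem9 (-0.20, 0.38, -0.03) and Tpt1 (-0.15, 0.23, 0.03). In SAHA rats it differed for 5 probes, none with a gene symbol. For SAHA against vehicle limma found 0 probes in home cage rats (195 with an unadjusted p under 0.05) and 0 in RPC rats (811), and array weights gave 1319 in RPC rats. The 629 fell to 2 without the arrays of low correlation and to 6 with median scaling, and the 5 became 156 and 6.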

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

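The tests of the region labels, of the share of genes on 1 side in both drug groups and of Tmem252 were chosen after the result was seen, and those of the quality axis and of the low-correlation arrays before, except that the count with array weights was set beside the latter afterwards.

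Arrays labelled CA1 carried dentate granule cell markers and arrays labelled DG carried CA1 neuron markers. An exchange of these 2 labels in the deposit could account for it: 28 of 28 arrays labelled CA1 scored under every array labelled DG. A wrong match of columns in the present work was excluded, since 84 of 84 columns had 1 region in header, title and characteristic. The test for tissue from the neighbouring region did not decide: Mpped1, Fibcd1 and Man1a1 were detected on 0 of 28 arrays labelled CA1, but 3 of 8 CA1 markers were detected on most of them (Ccn3 and Htr1a on 28, Wfs1 on 23). Of the 8, 7 were lower in labelled CA1 than in labelled DG, Wfs1 and Ccn3 by -3.79 each, and 1 was higher. These values argue against pieces that were still mainly the named tissue. Other mixtures stayed open. Htr1a and Pkp2 went against an exchange, and no test here could tell at which step the labels and the tissue parted.

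In the fits within regions, RPC changed many probes in labelled CA1 of vehicle rats and few in labelled CA3, but all 84 arrays in 1 fit called 2299 in labelled CA3. That fit takes 1 spread per probe over the 3 regions. With 3 of 7 vehicle RPC arrays of labelled CA3 of low correlation, its p-values may be too small there. Along the first component within groups (42.02% of the variance), which array quality may drive, the called changes had a correlation of -0.531 with its loading, and all probes one of -0.458, so this could not be told apart from a response. Whether low-correlation arrays hid changes in labelled CA3 stayed open: 1 probe was called without them, but that left 4 of 7 vehicle RPC arrays and so cost power, and array weights called 429. Of the called probes 91.5% lay on the same side in SAHA rats. Probes that move together along that component could fall on 1 side as a block. The share therefore could not exclude a difference private to the vehicle rats.

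Tmem252 was lower after SAHA in every region. Fewer vessel cells could not account for it, since the median change of endothelial markers was at most 0.0865 of the fitted change of Tmem252. That ratio is not exact: it came from home cage rats in labelled CA1 (-0.15 against -1.74), where no SAHA array detected Tmem252. A few rats did not carry the difference, since 39 of 42 SAHA arrays lay under every vehicle array of their contrast, and the other 3 were those of SAHA RPC replicate 1. That replicate may have had no drug response, since a score of 30 other genes, called for SAHA in home cage rats averaged over regions, placed it under the other SAHA RPC arrays and within the vehicle RPC arrays in 3 of 3 regions (0.0630, -0.0392 and -0.0102). An exchange with a vehicle RPC rat was excluded, as 0 of 21 vehicle RPC arrays scored over the SAHA median.

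Single arrays far from the other 6 of their group were found in 20 of 180 groups of values (11.1%), where chance gives about 1 in 20. Among shares detected it was SAHA RPC replicate 2 of labelled DG (49.98% against 45.82 to 47). Among median correlations these were replicate 5 of SAHA HC (0.9721), 6 of vehicle HC (0.9752) and 1 of vehicle RPC (0.9744) in labelled CA1, replicate 4 of SAHA RPC (0.9352) and 6 of vehicle RPC (0.8142) in labelled CA3, and replicate 7 of SAHA HC in labelled DG (0.9877). In labelled CA1, SAHA RPC replicate 1 had Phf13 at 8.522 (others 9.111 to 9.318) and Yeats4 at 10.32 (9.909 to 10), and vehicle RPC replicate 1 had Nr4a2 at 9.608 (8.384 to 8.74) and Sgk1 at 13.12 (12.35 to 12.66). In labelled DG they were Nfkbia at 11.6 in vehicle HC replicate 5, Npas4 at 5.888 in vehicle HC replicate 1, Csrp2 at 7.608 in vehicle RPC replicate 3, Slc40a1 at 7.604 in vehicle RPC replicate 7 and Junb at 10.64 in vehicle RPC replicate 1. The others there were Tie1 at 7.587 in SAHA RPC replicate 1, Dusp1 at 12.11 and Nrep at 6.741 in SAHA RPC replicate 3, and Enc1 at 9.033 in SAHA HC replicate 1.

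Apold1 had a drug by behaviour interaction of 0.8915 in labelled DG, a call that ended with the replicate block (adjusted p = 0.11) and in the fit of all 84 arrays (0.423, range over settings from 0.00557). The fitted interaction of ILMN_1350899 in labelled CA1 was -1.034. That probe was detected on 0 of 7 vehicle home cage arrays, so the value was not read as a size. The RPC response differed among regions for 629 probes in vehicle rats, with Arsl (adjusted p = 0.003672), Tmem9 and ILMN_1362029 (0.008156 each), and ILMN_1369780 and Tpt1 (0.008475 each) in front. It differed for 5 probes in SAHA rats: ILMN_1362029 and ILMN_1530195 (0.001356 each), ILMN_1364624 and ILMN_1649830 (0.03879 each) and ILMN_1530354 (0.04639).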

How the results depend on the processing

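Counts of called probes moved by over 1.5 times in 138 refits and did not in 305, and other counts did in 18 and did not in 43. Calls of named genes were lost in 83 and gained in 13, those of lists in 57 and 4, and region markers gained 5 and reversed 1. A gene or list past the threshold in neither setting counted as unchanged whatever its sign. The cause was not tested for any of these.

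With all 84 arrays in 1 fit with the rat as block, counts in labelled CA1 were 2 for SAHA in home cage rats, 29 for SAHA in RPC rats and 124 for RPC in SAHA rats; in labelled CA3 11 for SAHA in RPC rats, 2299 for RPC in vehicle rats (1015 higher, 1284 lower) and 14 for RPC in SAHA rats. In labelled DG they were 4, 19 for RPC in vehicle rats, 45 for RPC in SAHA rats and 0 for the interaction. With array weights, labelled CA1 had 7 for SAHA in home cage rats, 83 in RPC rats, 1373 for RPC in vehicle rats, 918 in SAHA rats and 11 for the interaction. Labelled CA3 had 7, 1, 429 and 28 for the first 4, labelled DG 17 and 28 for SAHA and 334 for RPC in SAHA rats, and differences among regions numbered 1319 for SAHA in RPC rats, 1772 for RPC in vehicle rats and 411 in SAHA rats.

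The authors' values gave 413 for RPC in vehicle rats and 0 for the interaction in labelled CA1, with 366 and 9 region differences for RPC in vehicle and SAHA rats; Chgb, labelled CA1 against CA3, was reversed (0.0843 in z-score units). Median scaling gave 2 for SAHA in RPC rats and 124 for RPC in vehicle rats in labelled CA1, 1 and 5 for RPC in vehicle and SAHA rats in labelled CA3, 1.0e+02 for RPC in SAHA rats in labelled DG (0.643 of the count) and 6 region differences for RPC in vehicle rats. No filter gave 1 for SAHA in RPC rats, 352 for RPC in vehicle rats, 1.6e+02 (0.639 of the count) in SAHA rats and 0 for the interaction in labelled CA1, 1 for RPC in SAHA rats in labelled CA3, 5 for SAHA in RPC rats and 100 for RPC in SAHA rats in labelled DG, 14511 for CA1 against CA3, and 1 and 290 region differences for SAHA in RPC rats and RPC in vehicle rats. The replicate block gave 2 and 0 (interaction) in labelled CA1, 0 for RPC in SAHA rats in labelled CA3, and 5 for SAHA in home cage rats and 0 for the interaction in labelled DG.

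The strict filter, which drops the dim Tmem252, gave 0, 0 and 1 for SAHA in home cage rats, 0 for the interaction in labelled CA1, 5397, 5117 and 5052 for the region pairs and 0 region differences for RPC in SAHA rats. Without low-correlation arrays there were 552 for RPC in SAHA rats and 0 for the interaction in labelled CA1, 1 and 5 for RPC in labelled CA3, and 2 and 156 region differences for RPC. Averaged SAHA counts were 349 there and 112 with median scaling.

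Leaving out each array in turn, the lowest and highest counts in labelled CA1 were 1 and 4 for SAHA in home cage rats, 1 and 65 in RPC rats, 328 and 724 for RPC in vehicle rats, 102 and 341 in SAHA rats and 0 and 1 for the interaction. In labelled CA3 they were 1 and 1, 0 and 4, 2 and 4, 0 and 3, and 0 and 0. In labelled DG they were 1 and 16, 4 and 22, 23 and 51, 98 and 254, and 1 and 2.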

Other observations

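The tests in this part were chosen after the result was seen. Averaged over regions and behaviours, 171 of 11403 probes differed between SAHA and vehicle (63 higher, 108 lower; limma with the rat as block; 349 without the low-correlation arrays and 112 with median scaling). Tmem252 changed most (-1.45, adjusted p = 1.25e-22), a size that rested partly on SAHA arrays that did not detect it. The block took 1 correlation for all probes (-0.0108), so same-numbered arrays of different regions counted almost as independent. SAHA RPC replicate 1 had the highest Tmem252 level of its group in labelled CA1, CA3 and DG (6.715, 7.315 and 7.521). If a number marks 1 rat, the p-values of Tmem252 and of other genes that differ between rats may be too small. The lower genes included Ctla2a (-0.45), the endothelial surface gene Cd93 (-0.43), Gadd45g (-0.41), Slc19a3 (-0.40), Kank3 (-0.38), Nfkbia (-0.33) and the endothelial junction gene Esam (-0.26). Slc40a1 (0.37, adjusted p = 1.34e-07), the tight junction gene Ocln (0.35), Phf13 (0.32), Csrp2 (0.29) and the transcription factor Ets1 (0.29) were among the higher ones. These genes had 1 sign in 6 of 6 contrasts, and they were named after their values were seen. They were called on the average of the same 6 contrasts, so the choice itself favours 1 sign. Over all probes, the SAHA changes of home cage and RPC rats correlated with r = -0.146, -0.101 and 0.361 in labelled CA1, CA3 and DG. Of 18 glucocorticoid-responsive genes 2 fell, of 25 immediate early genes 3 and of 6 endothelial markers 2, with 0 rises, and these were the 3 lists past the threshold at the preset correlation (no block). The immediate early gene Dusp1 was among these falls (-0.23) but kept its sign in 3 of 6 contrasts only. It stood at -0.63, -0.53 and -0.51 in home cage rats and at 0.05, 0.15 and 0.10 in RPC rats (labelled CA1, CA3 and DG). With an estimated correlation glucocorticoid-responsive genes held (adjusted p = 0.0333 with an estimated correlation), and immediate early genes and endothelial markers did not (adjusted p = 0.132 and 0.2 with an estimated correlation). Of 11 inflammation genes 3 fell and 1 rose, which was not past it as a list (adjusted p = 0.365).

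Red blood cell markers of same-numbered arrays moved together across the regions, with a mean correlation of 0.770 (permutation p = 1e-04, the smallest p that the shuffles can give). The number may mark 1 rat in the 3 regions. Interneuron (0.338, permutation p = 0.005) and choroid plexus markers (0.366, permutation p = 0.004) moved together less, among 13 marker lists tried. Over all probes the number within a group explained little (consensus correlation -0.0108).

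For each fit 100 splits of the same arrays were counted, the real one included, by how many gave at least as many calls, and then by the highest count of another split. For SAHA in home cage rats these were 6 (22) in labelled CA1, 1 (0) in labelled CA3 and 3 (42) in labelled DG, so the single call in labelled CA1 is not rare as a count, although the call is Tmem252. For SAHA in RPC rats they were 3 (173), 100 (4565) and 1 (5). For RPC in vehicle rats they were 1 (199), 3 (3321) and 1 (0), and for RPC in SAHA rats 1 (13), 1 (1) and 1 (57). For the interaction they were 4 (1259), 100 (0) and 2 (1). For differences among regions they were 100 (3) and 100 (4132) for SAHA in home cage and RPC rats, and 5 (1751) and 2 (99) for RPC in vehicle and SAHA rats. For labelled CA1 against CA3 they were 1 (3230), for CA1 against DG 1 (1), for CA3 against DG 1 (3019) and for the averaged SAHA contrast 1 (7). Splits with more calls than the real one, as in labelled CA3, point to a structure of the samples, and what it was, such as the arrays of low correlation, was not tested. The 629 region differences were not rare beside 1751.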
